A study of Mus musculus with 11 samples.

How the data were processed

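RNA was sequenced from Tmem119-positive microglia sorted from the cerebrum of 11 aged mice, with 3 WT, 3 Csf1r_het, 3 Csf2_het and 2 Dhet libraries. Reads were quantified with kallisto 0.43.1 on mm10 and normalized with DESeq2, per the submitters' processing notes, and the version of DESeq2 is not given in the sources used here. The deposited signal is 1 value per gene and library, a gene count that the authors divided by a size factor for each library, and is called a normalized count below. The table held 14739 genes, 11566 of them protein coding, with an Ensembl identifier, position and symbol for each. Any filter that the authors put on genes is not given in the sources used here. Of the identifiers, 14723 matched the GENCODE vM21 annotation without regard to version, and 13543 genes had the same chromosome, start and end there. Coordinates are those of the deposited table, and 7 genes that shared a symbol were named by identifier.

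In each library the values were whole multiples of a single step, which is what 1 read was worth. Divided by that step, 100% of the values came out whole within 0.02 reads, which gave the reads and the depth of each library. The depths ran from 21037819 reads (Csf1r_het replicate 1) to 53081638 reads (Csf2_het replicate 2). Floors for genes at 0 used 3 reads over the group, and the interval for a gene with few reads was a 95% exact Poisson interval.

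The groups came from the sample labels. The test for each kind of value, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That plan named edgeR for raw counts and limma for normalized values, so limma was the test here. Genes with a mean normalized count of at least 10 were tested, which kept 13223 and left out 1516. Values were log2(normalized count + 1), so fold changes of low genes are understated. A single limma fit with a trended prior covered the 4 groups, with 7 residual and 5.90 prior degrees of freedom. Contrasts were each heterozygous group against WT, Dhet against each single heterozygote and the interaction, with Benjamini-Hochberg adjustment at 0.05 within each contrast. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. The edgeR quasi-likelihood test on the recovered reads, added after the data were seen, tested 13703 genes and called 100 in Csf1r_het, 458 in Csf2_het, 26 in Dhet, 2 for Dhet against Csf1r_het, 3 for Dhet against Csf2_het and 201 for the interaction.

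The 32 lists covered homeostatic and disease-associated microglia, CSF ligands and receptors, CSF-2 and STAT5 response, interferon response, antigen presentation, inflammatory cytokines, complement, oxidative stress, oxidative phosphorylation, glycolysis, ribosomal proteins, lysosome, lipid handling, proliferation, TGF-beta signalling, ER stress, immediate early and dissociation genes, neurotrophic genes, sex-linked genes and markers of oligodendrocytes, their precursors, astrocytes, neurons, endothelium, mural cells and fibroblasts, T and NK cells, B cells, neutrophils, monocytes, border macrophages and erythroid cells. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. With an estimated correlation camera called 0 lists in each of the 6 contrasts. Fry tests whether the genes of a list move on balance in 1 direction, without comparing them with other genes.

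Genes were named by rule. The rule took the measured CSF ligands and receptors in every contrast and, among called genes with a mean of at least 50, the 8 with the largest rise and the 8 with the largest fall. It also took up to 4 called members of each pathway list, or the 2 with the lowest p where none was called, and up to 2 members of each marker and technical list. Predicted gene names were skipped in the second part, 1 among the higher and 0 among the lower genes in Csf1r_het, 4 and 1 in Csf2_het, 2 and 2 in Dhet and 1 and 0 for the interaction. Some genes that the rule took are not reported here. Ddx3y and Xist in the account of the libraries, and the genes named among the further observations, were chosen after their values were seen.

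The fit was tested on simulated data made from the real means and library sizes. For Csf1r_het against WT it called 2 of 67 genes changed by a log2 fold of 1, 18 of 65 changed by 2 and 51 of 66 changed by 4, with 4 false calls among 12971 unchanged genes. For Csf2_het the numbers were 2 of 68, 17 of 66 and 38 of 65, with 3 of 12963. For Dhet they were 1 of 68, 10 of 66 and 36 of 66, with 3 of 12965. Camera found the changed set of the Csf1r_het simulation (adjusted p = 4.94e-09) and called 0 of 50 unchanged sets. Small changes were thus mostly missed at this group size. Genes were drawn independently in these simulations, so they do not test calls among genes that move together. The estimated correlation of the real ribosomal list, for example, was 0.916.

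Alternatives were DESeq2 and edgeR on the recovered reads, median-centred log2 values, other pseudocounts (0.1 and 10), other minimum means, other thresholds (0.01 and 0.1), a minimum log2 change of 1, age as a covariate, leaving out the 24-month libraries, only the groups compared, the replicate number as a block and each library left out in turn. Leaving out Csf1r_het replicate 2 and WT replicate 2 together, which lay farthest out on the first principal components, and the monocyte marker mean as a covariate were added after the data were seen, as were 3 further gene lists. Csf2, Il34 and Csf3 were not analysed here.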

Results

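Gene expression was measured by bulk RNA sequencing in Tmem119-positive microglia sorted from the cerebrum of aged C57BL/6 mice. Csf1r encodes the receptor for CSF-1 and IL-34, on which microglia depend for survival, and Csf2 encodes GM-CSF (CSF-2), a cytokine that signals through the receptor chains encoded by Csf2ra and Csf2rb. The 11 libraries formed 4 groups: 3 wild-type libraries (WT), 3 from Csf1r+/- mice (Csf1r_het), 3 from Csf2+/- mice (Csf2_het) and 2 from mice that lacked a copy of both genes (Dhet). The series asks how loss of a Csf1r copy, of a Csf2 copy or of both alters aged microglia. The mice were 21 months old, except that Csf1r_het replicate 1 was 20 months and Csf1r_het replicate 2 and Dhet replicate 2 were 24 months. Between 21037819 reads (Csf1r_het replicate 1) and 53081638 reads (Csf2_het replicate 2) were assigned to genes. Thus 1 read was worth 0.479 to 1.48 normalized counts. Haemoglobin genes took 16.1% of the counts in WT replicate 1 and 58.8% in Csf1r_het replicate 2, with the other libraries in between. Csf1r_het replicate 2 had 15.6% of genes at 0, against 4.98% to 9.88% in the other libraries. Dhet replicate 2 stood apart in sex-linked genes: it held 717 normalized counts of Ddx3y and 4.02 of Xist, against at most 16.3 of Ddx3y and at least 3011 of Xist elsewhere. Values below are normalized counts as group mean ± SD, and log2 fold changes carry their standard error (SE). Limma p-values measure the spread between these mice. Camera p-values at the preset correlation compare the genes of a list with other genes, taken as nearly independent. They do not measure that spread.

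Csf1r was examined first, because its copy number defines the groups. Csf1r (ENSMUSG00000024621.15) lies on chromosome 18, 61105572 to 61132149, on the forward strand of mm10. The WT libraries held 93319, 41261 and 63538 normalized counts of Csf1r. The Csf1r_het libraries held 17017, 40567 and 24022, the Csf2_het libraries 53873, 58211 and 66762, and the Dhet libraries 40151 and 30254. The 5 libraries from mice with a deleted Csf1r copy averaged 30402 ± 10226 and the 6 others 62827 ± 17391, a ratio of 48.4%. All 5 lay below all 6 (log2 difference -1.08, 2-sided exact permutation p = 0.00433 over 462 regroupings). Within Csf2 genotypes the ratio was 41.2% for Csf1r_het to WT and 59.0% for Dhet to Csf2_het. Over all genes tested, the limma comparisons of Csf1r did not pass, with an adjusted p = 0.184 in Csf1r_het and an adjusted p = 0.743 for Dhet against Csf2_het. The deletion in Csf2 was not checked from expression, since Csf2, Il34 and Csf3 were not analysed here.

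Among the other CSF receptor genes, the shared GM-CSF receptor chain Csf2rb (ENSMUSG00000071713.4, chromosome 15, 78325990 to 78351000) fell in both single heterozygotes. It averaged 5070 ± 1233 in WT, 1854 ± 700.2 in Csf1r_het, 1356 ± 61.6 in Csf2_het (n = 3 each) and 1829 ± 181 in Dhet (n = 2). Its log2 fold change was -1.49 (SE 0.32, limma adjusted p = 0.0423) in Csf1r_het and -1.87 (SE 0.32, limma adjusted p = 0.00654) in Csf2_het. In Dhet it was -1.44 (SE 0.36), which did not pass (limma adjusted p = 0.136). The GM-CSF-specific chain Csf2ra (ENSMUSG00000059326.6, chromosome 19, 61224402 to 61228418) fell in Csf2_het, from 2991 ± 1191 to 925 ± 144 (log2 fold change -1.63, SE 0.33, limma adjusted p = 0.0157). Csf2ra did not pass in Csf1r_het (-1.28, limma adjusted p = 0.0771) or in Dhet (-1.27, limma adjusted p = 0.222). The paralog Csf2rb2, which serves IL-3, had log2 fold changes of -0.40, -0.72 and -0.35 in Csf1r_het, Csf2_het and Dhet, none of which passed. Il3ra, the specific IL-3 receptor chain, had -0.53, -2.14 and -2.03, which did not pass either. Csf1, a ligand of Csf1r, and Csf3r, the G-CSF receptor, did not pass either, with 0.25, 0.46 and 0.95 for Csf1 and -0.75, -0.13 and 0.16 for Csf3r. Reads shared between Csf2rb and Csf2rb2, which are close copies, make the split between these genes uncertain. Neither Csf2rb in Csf1r_het nor Csf2ra in Csf2_het kept its call in every fit with 1 library left out, while Csf2rb in Csf2_het did. Monocyte markers also lay lower in these groups, with a median log2 fold change of -1.42 in Csf1r_het and -3.21 in Csf2_het. With the monocyte marker mean as a covariate limma called 0 genes in either group. Whether the receptor genes fell in microglia or along with monocyte-lineage cells was not tested.

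**Figure D1:**
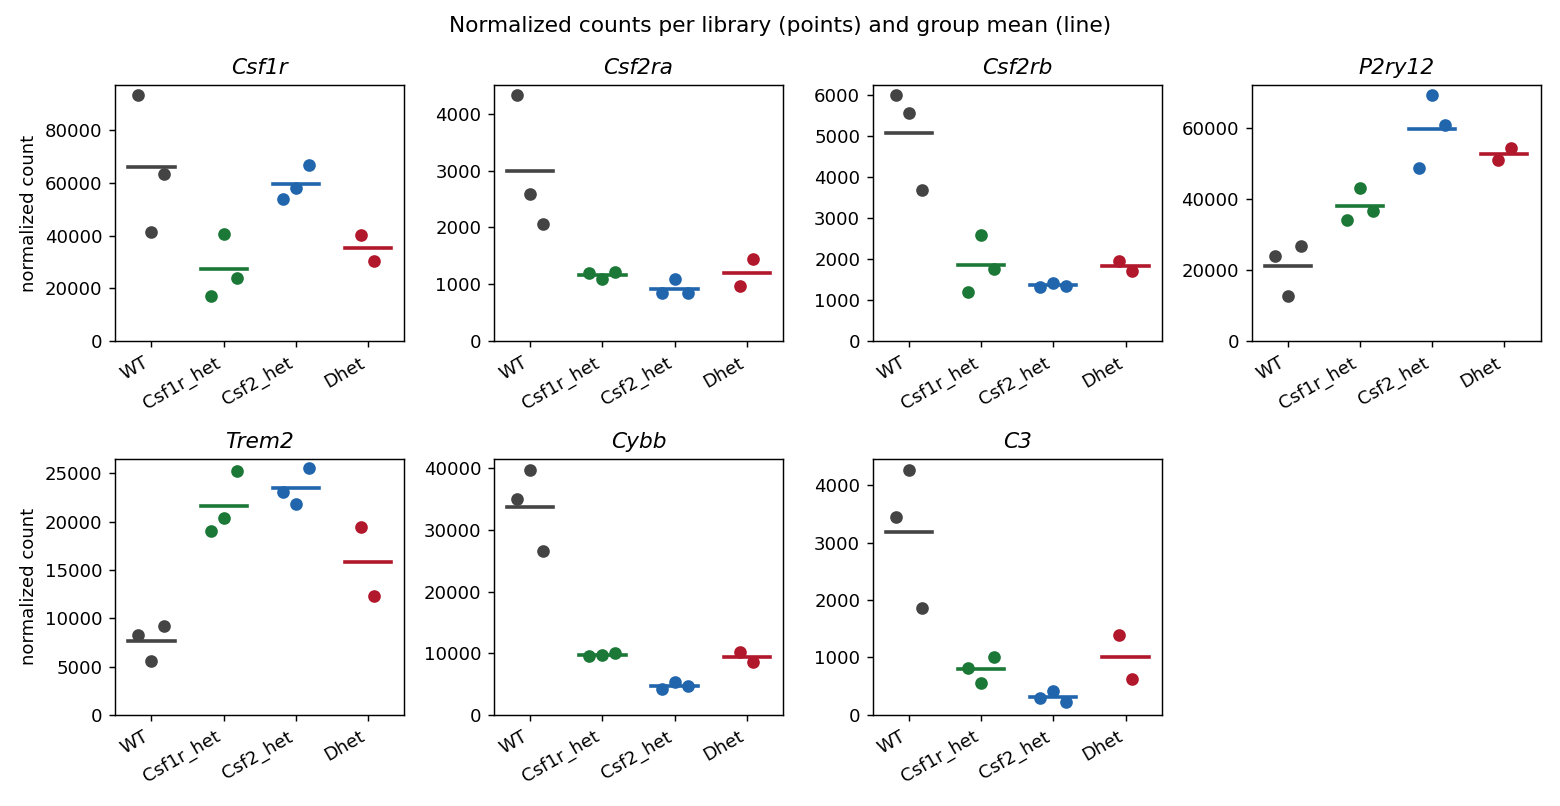
Normalized counts (vertical axes, from 0) of 7 genes in each library (points) by group (horizontal axes), with a line at the group mean. The Csf1r counts of the 5 libraries lacking a Csf1r copy lie below those of the 6 others, and P2ry12 and Trem2 lie above WT and Csf2rb, Cybb and C3 below WT in all 8 heterozygous libraries.

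Csf1r_het against WT asks what loss of a Csf1r copy does alone. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, fell 3.41-fold in Csf1r_het, from 33764 ± 6711 to 9777 ± 196 (n = 3 each, log2 fold change -1.77, SE 0.28, limma adjusted p = 0.0157). Trem2, a lipid-sensing receptor of microglia, rose 2.85-fold, from 7681 ± 1868 to 21565 ± 3292 (1.51, SE 0.32, limma adjusted p = 0.0408). Plin2, which coats lipid droplets, fell 4.56-fold (-2.19, SE 0.29, limma adjusted p = 0.00929), and Pirb, an inhibitory immunoglobulin-like receptor of myeloid cells, fell 6.17-fold (-2.63, SE 0.33, limma adjusted p = 0.00855). In all, 57 genes were higher and 117 lower at an adjusted p of 0.05. With the log2 values of each library centred on their median, the split was 82 higher and 84 lower. The median of all genes lay at -0.12, which is the reference for the changes given here.

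The genes that rose most in Csf1r_het were Sbspon, an extracellular matrix gene (4.36, SE 0.95), Nap1l5 (3.30), Pifo, a gene of primary cilium disassembly (2.75), the glutathione transferases Gstm2 (2.53) and Gsta4 (2.40), Fam92a (2.50), Enho (2.29) and Cystm1 (2.28). Those that fell most were the dipeptidase gene Dpep2 (-3.25), the ERK phosphatase Dusp5 (-3.16), the transcriptional repressor Nfil3 (-2.85), the G protein-coupled receptor Gpr35 (-2.71), Def6 (-2.71), the monocarboxylate transporter Slc16a3 (-2.69), Pirb and Rasgrp4, an activator of Ras in myeloid cells (-2.59). Genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, also rose, with a median of 1.61 and 2 of 10 called. That list was added after the data were seen (unadjusted camera p = 0.042 with an estimated correlation). Whether the genes that rose most share a source with it was not tested. Of 23 disease-associated microglia genes, 3 rose, namely Trem2, the secreted phosphoprotein Spp1 (2.16, SE 0.46) and the cystatin Cst7 (1.75, SE 0.37), with 5 when adjusted over the list alone. The list had a median log2 fold change of 0.25 and a camera adjusted p = 0.0063, and an adjusted p = 0.614 with an estimated correlation. Of 19 homeostatic microglia genes none passed over all genes and 1 passed adjusted over the list alone. Siglech reached 1.31 (SE 0.34, limma adjusted p = 0.087), and the list's median was 0.41 with a camera adjusted p = 0.00285 and an adjusted p = 0.754 with an estimated correlation. That median was 0.083 without WT replicate 2 and -0.15 without both WT replicate 2 and Csf1r_het replicate 2. The complement list held 2 of 13 genes that fell, the integrin chain Itgb2 (-1.83, SE 0.31) and C3 (-1.95, SE 0.43), with 2 adjusted over the list alone. In the oxidative stress list 2 of 23 fell, among them Cybb, and 6 passed adjusted over the list alone, 1 of them higher. In the TGF-beta list 1 of 12 genes fell, the matrix protein Tgfbi (-2.40, SE 0.43). Il1b, an inflammatory cytokine, did not pass (-1.81, limma adjusted p = 0.0595).

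Lists of other processes and cell types were called in this comparison. Immediate early and dissociation genes, which sorting can induce, had a median of -1.16 with 2 of 17 that fell, Klf2 (-2.23) and Dusp1 (-2.31), 5 adjusted over the list alone. Their camera adjusted p was 4.9e-05, and the adjusted p = 0.577 with an estimated correlation. Monocyte markers had a median of -1.42, with 1 of 8 that fell and 3 adjusted over the list alone. Their camera adjusted p = 0.00175 became an adjusted p = 0.577 with an estimated correlation. Neuron markers had a median of 2.13 with 8 of 8 above 0 and none that passed (camera adjusted p = 0.00175, adjusted p = 0.577 with an estimated correlation). Oxidative phosphorylation had a median of 0.48 (camera adjusted p = 0.00175, adjusted p = 0.614 with an estimated correlation), but 0.047 with edgeR and 0.064 with DESeq2. Lipid handling had -0.62 (0.0369, adjusted p = 0.577 with an estimated correlation) and glycolysis -0.55 (0.0412, adjusted p = 0.754 with an estimated correlation). CSF ligands and receptors had -0.75 (0.0232, adjusted p = 0.614 with an estimated correlation) and astrocyte markers 0.77 (0.0455, adjusted p = 0.754 with an estimated correlation). In all 27 named calls the 3 Csf1r_het libraries lay beyond the 3 WT libraries. These genes were chosen as called between the same libraries, so the 10% that chance gives among unselected genes is no reference for them.

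The number of calls in Csf1r_het depended on single libraries. Limma called 0 genes without WT replicate 1 (1474 at an unadjusted p under 0.05), 0 without Csf1r_het replicate 3 (1939 unadjusted), 21 without Csf1r_het replicate 1, and 38 without Csf1r_het replicate 2. It called 53, 48 and 87 without Csf2_het replicates 1, 2 and 3 and 442 without WT replicate 2. None of the 27 named calls held in every such fit. With only the 6 libraries of these groups in the fit it called 0 (1717 unadjusted), edgeR called 100 and DESeq2 828. Of the list calls, those for disease-associated genes, oxidative phosphorylation, immediate early genes and neuron markers held without any 1 library. The oxidative phosphorylation median nevertheless ran from 0.17 without WT replicate 1 to 0.89 without WT replicate 2, and the disease-associated median reached 0.54 without WT replicate 1. The astrocyte median ran from 0.028 without WT replicate 2 to 1.27 without WT replicate 3, the homeostatic median reached 0.73 without WT replicate 3, the CSF median -1.22 without WT replicate 3 and the glycolysis median -0.90 without WT replicate 2. The homeostatic (camera adjusted p = 0.326) and monocyte (0.0505) calls were lost without WT replicate 2. The CSF call was lost without WT replicate 1 (0.0674), Csf1r_het replicate 1 (0.154) or Csf1r_het replicate 3 (0.0596). The lipid call was lost without WT replicate 1 (0.0847), Csf1r_het replicate 1 (0.103) or Csf1r_het replicate 3 (0.0621). The glycolysis call was lost without WT replicate 1 (0.0839), WT replicate 3 (0.177), Csf1r_het replicate 2 (0.0514) or Csf1r_het replicate 3 (0.135). The astrocyte call was lost without WT replicate 1 (0.0569), WT replicate 2 (0.491), Csf1r_het replicate 2 (0.335), Dhet replicate 1 (0.0586) or Dhet replicate 2 (0.0567).

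Csf2_het against WT asks what loss of a Csf2 copy does alone. Monocyte markers were the group with the lowest median of the lists tested. Their 8 tested genes all fell, among them the chemokine receptor Ccr2, which brings monocytes out of the marrow (9795 ± 5712 in WT, 752 ± 220.1 in Csf2_het, n = 3 each, log2 fold change -3.53, SE 0.45, limma adjusted p = 0.00116). Of 19 genes typical of resting microglia 3 rose. The purinergic receptor P2ry12 went from 21147 ± 7353 to 59671 ± 10322 (1.55, SE 0.39, limma adjusted p = 0.0464). Siglech rose by 1.43 (SE 0.34, limma adjusted p = 0.0375) and the transcription factor Sall1 by 1.5 (SE 0.38, limma adjusted p = 0.049). Cybb fell 7.09-fold, to 4722 ± 591 (-2.83, SE 0.28, limma adjusted p = 0.000286), and C3 fell 9.94-fold, from 3189 ± 1222 to 312 ± 98.1 (-3.31, SE 0.43, limma adjusted p = 0.00124). In all, 107 genes were higher and 375 lower.

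Of the 19 homeostatic genes tested, 19 had a positive log2 fold change in Csf2_het, 3 rose over all genes and 10 rose adjusted over the list alone. The median was 1.09 (camera adjusted p = 8.79e-09, adjusted p = 0.508 with an estimated correlation), and it turned to -0.53 with the monocyte marker mean, which largely follows the groups, as a covariate. The disease-associated and interferon medians given next also turned sign with that covariate. Of 23 disease-associated genes, 5 rose, among them Trem2 (1.64, SE 0.32), Spp1 (2.08, SE 0.46) and the cholesterol hydroxylase Ch25h (2.42, SE 0.49), and 1 fell, the galectin Lgals3 (-2.28, SE 0.35). Adjusted over the list alone, 10 passed, 8 of them higher, and the median was 0.54 (camera adjusted p = 0.00729, adjusted p = 0.53 with an estimated correlation). Of 25 interferon response genes 6 fell, among them Ifi204 (-2.31), Slfn2 (-2.53), Oas1a (-2.14) and the nucleic acid sensor Zbp1 (-2.72), and 10 passed adjusted over the list alone. Their median was -1.42 (camera adjusted p = 2.03e-06, adjusted p = 0.514 with an estimated correlation). Of 21 antigen presentation genes, the MHC class II genes H2-Ab1 (-1.64, SE 0.38) and H2-Aa (-1.60, SE 0.40) fell over all genes and 14 fell adjusted over the list alone, with a median of -1.16 (camera adjusted p = 6.89e-06, adjusted p = 0.508 with an estimated correlation).

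The phagocyte oxidase genes Rac2 (-1.65) and Ncf4 (-1.82) fell with Cybb. In all, 4 of 23 genes of the oxidative stress list fell, and 5 passed adjusted over the list alone, 1 of them higher. The list's median was -0.62 (camera adjusted p = 0.0252, adjusted p = 0.386 with an estimated correlation). In the complement list C3, Itgb2 (-1.73, SE 0.31) and properdin, Cfp (-3.23, SE 0.61), fell, while 9 of its 13 genes passed adjusted over the list alone, 4 of them higher. In the cytokine list Il1b fell (-2.78, SE 0.43) and the chemokine Ccl3 rose (1.99, SE 0.42). Lipid genes that fell numbered 5 of 28 and included Plin2 (-2.39), the nuclear receptor Pparg (-2.38) and the scavenger receptor Msr1 (-2.24), and 7 passed adjusted over the list alone, 2 of them higher. Slc16a3 (-2.13) was the 1 gene of 17 in the glycolysis list that fell, with 5 adjusted over the list alone, and Tgfbi (-3.62, SE 0.43) the 1 of 12 in the TGF-beta list. The glycolysis median was -0.46 (camera adjusted p = 0.0173, adjusted p = 0.662 with an estimated correlation) and that of CSF ligands and receptors -0.72 (0.0281, adjusted p = 0.588 with an estimated correlation). That of oxidative phosphorylation was 0.32 (0.024, adjusted p = 0.643 with an estimated correlation), but 0.093 with edgeR and 0.11 with DESeq2, and that of 41 ribosomal protein genes -0.75 (0.000295, adjusted p = 0.806 with an estimated correlation). None of the ribosomal or oxidative phosphorylation genes passed.

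Beyond these lists, the genes that rose most in Csf2_het were Spink8 (1.91 ± 3.31 in WT, 845 ± 322 in Csf2_het), Rps3a3, Rps3a2, the adhesion gene Nectin3 (log2 fold change 6.43), Hmgcll1 (5.82), Sbspon (3.82), Ttll4 (3.02) and Meig1 (2.86). Rps3a2 (ENSMUSG00000062611.4, chromosome 14, 88123017 to 88123808) and Rps3a3 (ENSMUSG00000059751.7, chromosome 13, 108670603 to 108671397) lie apart from the ribosomal protein gene Rps3a1, of which they are near copies. Reads can be assigned to any of the 3, so their counts are uncertain. Rps3a2 went from 6.29 ± 4.46 in WT to 1283 ± 185 in Csf2_het and Rps3a3 from 1.94 ± 1.94 to 603 ± 201. The genes that fell most were the matrix proteoglycan Vcan, the adenylate cyclase Adcy4, Spag11b, Fam109b (-6.33), the autophagy gene Dram1 (-6.14), the RNA sensor Tlr8 (-5.82), Slco3a1 (-5.71) and the myeloid receptor Tarm1 (-5.68). Adcy4 and Spag11b had 0 reads in the 3 Csf2_het libraries and were at least 257-fold and at least 279-fold lower than in WT, taking 3 reads over the group as the floor. Vcan had 2 reads in Csf2_het, a WT to Csf2_het ratio of 702 with a 95% exact Poisson interval of 194 to 5790. These intervals and floors cover counting error only. Choroid plexus genes had a median of 1.26 in Csf2_het with 1 of 10 that rose (unadjusted camera p = 0.0796 with an estimated correlation). Whether the genes that rose most share a source with them was not tested.

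Among markers of other cells, the monocyte median was -3.21 (camera adjusted p = 4.49e-12, adjusted p = 0.128 with an estimated correlation), with 8 of 8 passing adjusted over the list alone, and the median was the same with Vcan at its floor. Of 5 border macrophage genes 1 fell, Clec12a (-2.26, SE 0.32), which monocytes also express. B cell markers had a median of -1.85 with 0 of 6 that passed and 1 adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.588 with an estimated correlation) and astrocyte markers 1.28 with 0 of 9 and 1 adjusted over the list alone (0.0141, adjusted p = 0.662 with an estimated correlation). Immediate early and dissociation genes had a median of -0.95 with 4 of 17 that fell, among them Klf2 (-3.16) and the nuclear receptor Nr4a1 (-2.94), 5 adjusted over the list alone. Their camera adjusted p was 0.000355, and the adjusted p = 0.53 with an estimated correlation.

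In all 48 named calls of Csf2_het the 3 libraries lay beyond the 3 WT libraries, which largely follows from their choice as called genes (chance gives 10% of unselected genes). Of these calls 17 held in every fit with 1 library left out, among them Csf2rb, Cybb, C3, Itgb2, Il1b, Lgals3, Plin2, Tgfbi and Ccr2. The count was 172 without WT replicate 1 and 173, 228 and 218 without Csf2_het replicates 1, 2 and 3, and 259 with only the 6 libraries of these groups in the fit. P2ry12, Siglech and Sall1 were not among the 17. EdgeR called 97 higher and 361 lower, 435 of them shared with limma, and DESeq2 401 and 837. The ribosomal call was lost without WT replicate 2 (camera adjusted p = 0.42), where the median turned to 0.11, and it was -1.23 without WT replicate 3. The oxidative phosphorylation median ran from 0.067 without WT replicate 3 to 0.71 without WT replicate 2 and the glycolysis median from -0.79 without Csf2_het replicate 2 to -0.22 without WT replicate 3. Without WT replicate 2 the median was 0.73 for homeostatic, 0.33 for disease-associated, -0.36 for oxidative stress and 0.61 for astrocyte genes, and the disease-associated median reached 0.82 without Csf2_het replicate 3. Further list calls were lost without WT replicate 1 for CSF genes (0.108) and oxidative phosphorylation (0.108) and without WT replicate 2 for astrocyte (0.273) and B cell markers (0.0662). They were also lost without WT replicate 3 for oxidative stress (0.0916), oxidative phosphorylation (0.296) and glycolysis (0.13), without Csf2_het replicate 1 for astrocyte markers (0.258) and without Csf2_het replicate 3 for glycolysis (0.125).

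**Figure D2:**
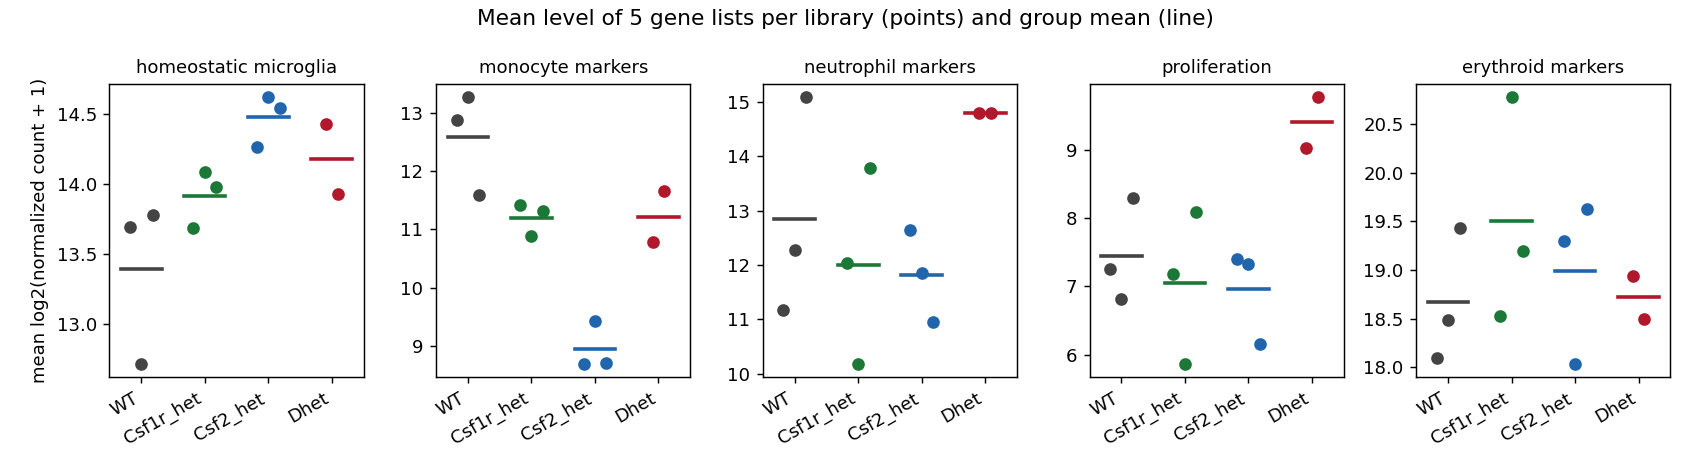
Mean log2(normalized count + 1) of 5 gene lists (vertical axes, not starting at 0) in each library (points) by group, with a line at the group mean. The monocyte mean is 12.6 in WT and 8.94 in Csf2_het, and the proliferation mean 7.45 in WT and 9.40 in Dhet. The neutrophil and erythroid means spread more within WT, Csf1r_het and Csf2_het than within Dhet.

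Dhet against WT asks what loss of a copy of both genes does. Tgfbi fell 5.62-fold in Dhet (-2.49, SE 0.48, limma adjusted p = 0.0399), from 9814 ± 5314 (n = 3) to 1521 ± 98.4 (n = 2), and Il1b fell 6.13-fold (-2.62, SE 0.48, limma adjusted p = 0.0338). Cybb fell 3.57-fold, to 9376 ± 1214 (-1.83, SE 0.31, limma adjusted p = 0.021), and Plin2 fell 4.12-fold, to 1127 ± 310 (-2.04, SE 0.32, limma adjusted p = 0.0146). In all, 4 genes were higher and 66 lower. The named genes among the 4 were Rps3a2 (1456 ± 111) and Rps3a3 (527 ± 69.8), as in Csf2_het, and the other 2 carry predicted names. Those that fell most were Adcy4 (0 reads in both Dhet libraries, at least 209-fold lower), the acute-phase gene Saa3 (-6.80, SE 1.15), Dpep2 (-4.73), Fcrl5 (-4.60), the heparan sulfate polymerase Ext1 (-4.52), the fatty acid binding protein Fabp4 (-4.30), Ms4a4a (-4.02) and Skint3 (-3.93).

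Proliferation genes stood out as a list in Dhet without a single member passing over all genes. All 23 had a positive log2 fold change, with a median of 2.0, and 4 passed adjusted over the list alone (camera adjusted p = 4.87e-11, adjusted p = 0.372 with an estimated correlation). The survivin gene Birc5 had 2.79 (SE 0.66, limma adjusted p = 0.113) and the microtubule regulator Stmn1 2.0 (SE 0.48, limma adjusted p = 0.12). Neutrophil markers lay beside them: all 10 were positive, with a median of 1.89 (camera adjusted p = 0.000594, adjusted p = 0.478 with an estimated correlation). That median was 0.89 with edgeR and 0.92 with DESeq2 and ran from 1.08 without WT replicate 1 to 3.06 without WT replicate 3. The granule genes Camp (2.65, limma adjusted p = 0.387) and Ngp (2.59, limma adjusted p = 0.488) did not pass. The homeostatic list had 19 of 19 above 0, a median of 0.78 and 0 that passed, with P2ry12 at 1.39 (limma adjusted p = 0.287) and Siglech at 1.11 (limma adjusted p = 0.343) (camera adjusted p = 8.05e-06, adjusted p = 0.478 with an estimated correlation). In the interferon list 1 of 25 fell, Ifi204 (-2.13, SE 0.42), 5 adjusted over the list alone, and the median was -0.80 (camera adjusted p = 0.000715, adjusted p = 0.478 with an estimated correlation). In antigen presentation 0 of 21 passed and 3 adjusted over the list alone, with H2-Aa at -1.83 (limma adjusted p = 0.124) and a median of -0.95 (camera adjusted p = 2.06e-06, adjusted p = 0.372 with an estimated correlation). Ribosomal protein genes had a median of -1.18 and 0 of 41 that passed (camera adjusted p = 5.32e-12, adjusted p = 0.478 with an estimated correlation).

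Among the other lists called in Dhet were disease-associated microglia (median 0.69, camera adjusted p = 0.0355, adjusted p = 0.478 with an estimated correlation) and CSF ligands and receptors (-0.84, 0.0418, adjusted p = 0.478 with an estimated correlation). Others were oxidative stress (-0.38, 0.0471, adjusted p = 0.372 with an estimated correlation), lipid handling (-0.23, 0.0342, adjusted p = 0.372 with an estimated correlation) and ER stress (0.51, 0.0471, adjusted p = 0.503 with an estimated correlation). Immediate early genes had a median of -0.39, with 1 of 17 that fell, Klf2 (-2.42, SE 0.45) (camera adjusted p = 0.0418, adjusted p = 0.578 with an estimated correlation). Adjusted over the list alone, 1 disease-associated, 2 CSF, 2 oxidative stress, 3 lipid, 0 ER stress and 3 immediate early genes passed, all of them lower, the disease-associated gene included. Monocyte markers had a median of -0.98, 0 of 8 that passed and 1 adjusted over the list alone (0.0138, adjusted p = 0.478 with an estimated correlation). Oligodendrocyte markers had a median of 1.59 (0.00599, adjusted p = 0.372 with an estimated correlation). Astrocyte markers had 1.44 (0.0049, adjusted p = 0.478 with an estimated correlation) and neuron markers 1.07 (0.0132, adjusted p = 0.478 with an estimated correlation), with none of their genes passing over all genes and 2, 0 and 0 adjusted over the list alone.

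Limma called 2 genes in Dhet without Dhet replicate 1, the 21-month library, and 174 without Dhet replicate 2. It called 6, 37 and 111 without WT replicates 1, 2 and 3, 42 without Csf1r_het replicate 1, and 44 and 42 without Csf2_het replicates 1 and 2. In all 16 named calls the Dhet libraries lay beyond the WT libraries, again among genes chosen as called (chance gives 20% of unselected genes), and none of these calls held in every such fit. With only the 5 libraries of these groups it called 0 (966 at an unadjusted p under 0.05), edgeR called 26 and DESeq2 361. The homeostatic, antigen presentation, ribosomal and proliferation calls held without any 1 library. The median changed in size, to -0.41 without WT replicate 2 for ribosomal, 0.43 without Dhet replicate 1 for homeostatic and -0.61 without Dhet replicate 2 for antigen presentation genes. Those of other called lists came as near 0 as 0.32 without Dhet replicate 1 for disease-associated, -0.55 without WT replicate 1 for CSF, -0.43 without WT replicate 1 for interferon and -0.17 without WT replicate 3 for oxidative stress genes. They were 0.18 without WT replicate 2 for ER stress, 0.81 without Dhet replicate 1 for oligodendrocyte, 0.65 without WT replicate 2 for astrocyte and -0.57 without WT replicate 2 for monocyte genes. They came as far from 0 as -0.40 without WT replicate 2 for lipid, -1.04 without Dhet replicate 1 for immediate early, -1.53 without WT replicate 3 for monocyte, 2.26 without WT replicate 3 for astrocyte and 2.60 without Dhet replicate 2 for neuron genes. With edgeR and DESeq2 the astrocyte median was 0.87 and 0.89 and the immediate early median -0.26 and -0.24. The interferon call was lost without Dhet replicate 2 (camera adjusted p = 0.161) and the neutrophil call without WT replicate 1 (0.0658). Without WT replicate 1 the monocyte (0.05), neuron (0.101), lipid (0.118), CSF (0.163), ER stress (0.05) and immediate early (0.191) calls were lost. Without WT replicate 2 the monocyte (0.0612), astrocyte (0.0748) and ER stress (0.454) calls were lost, and without WT replicate 3 the disease-associated (0.0642), CSF (0.0512) and oxidative stress (0.211) calls. Without Dhet replicate 1 the disease-associated (0.904), oxidative stress (0.0816), ER stress (0.195), oligodendrocyte (0.239), neuron (0.166) and monocyte (0.0816) calls were lost. Those lost without Dhet replicate 2 were the CSF (0.363), oxidative stress (0.148), lipid (0.128), ER stress (0.0811), astrocyte (0.0811) and immediate early (0.534) calls, the last of which turned direction. The oxidative stress call was also lost without Csf1r_het replicate 1 (0.0521), Csf1r_het replicate 2 (0.0675), Csf2_het replicate 1 (0.0512) or Csf2_het replicate 2 (0.0523). The ER stress call was also lost without Csf1r_het replicate 1 or Csf2_het replicate 1 (0.0512 each).

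**Figure D3:**
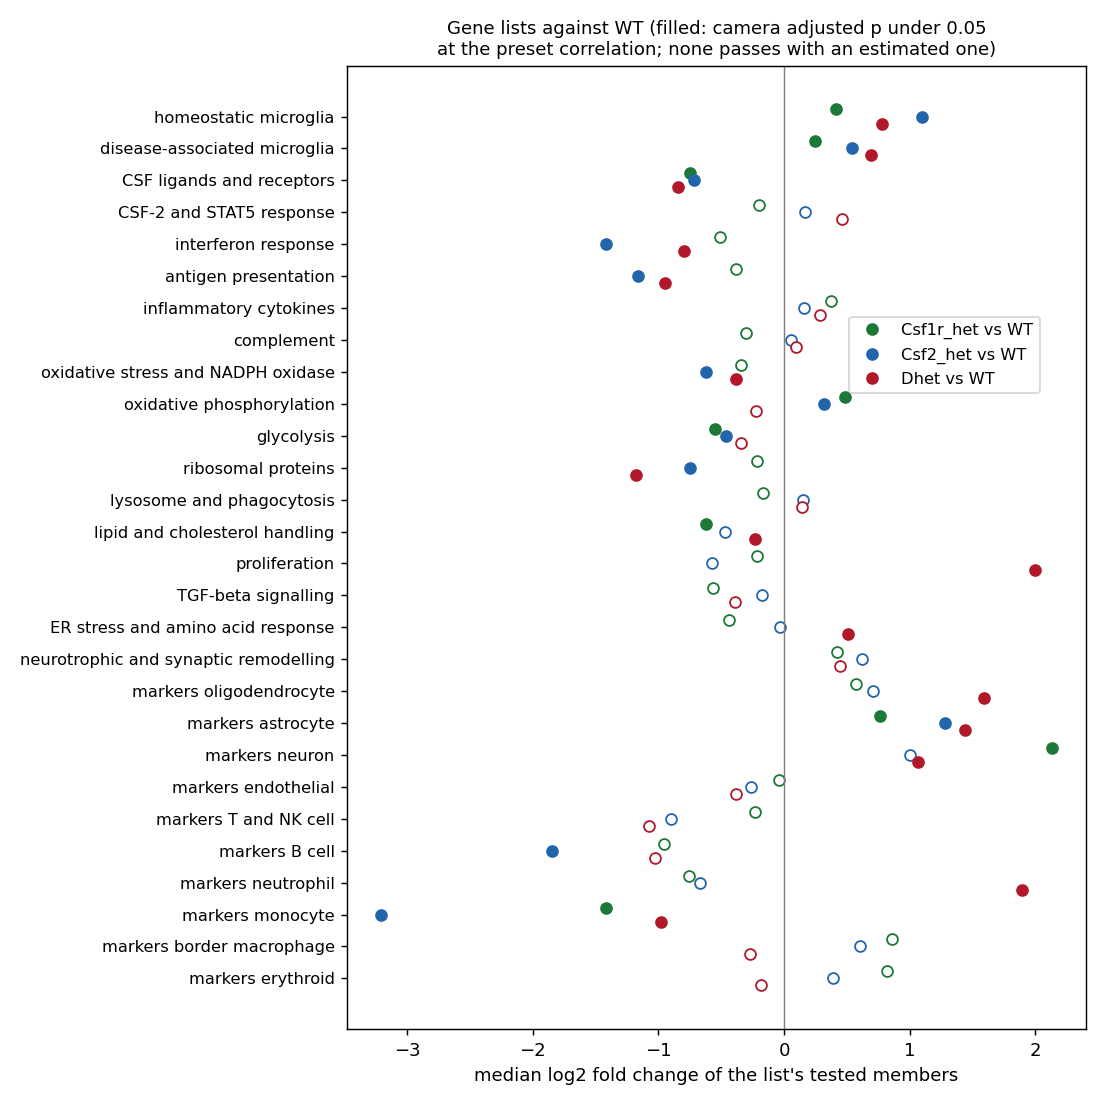
Median log2 fold change against WT (horizontal axis) of the fixed pathway and cell type lists with at least 5 tested members (vertical axis) in Csf1r_het, Csf2_het and Dhet. Filled points passed camera at the preset correlation and none passed with an estimated one. The monocyte median is -3.21 in Csf2_het and the proliferation median 2.0 in Dhet.

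Dhet against Csf1r_het asks what loss of a Csf2 copy adds when a Csf1r copy is already lost. The only call was Rps3a2, which rose by 7.89 (SE 0.96, limma adjusted p = 0.0236), from 6.29 ± 4.24 (n = 3) to 1456 ± 111 (n = 2). No gene was called lower, against 1390 genes in either direction at an unadjusted p under 0.05, and edgeR called 2 higher and 0 lower and DESeq2 37 and 81. Proliferation genes had 23 of 23 positive and a median of 2.11, with 12 passing adjusted over the list alone and Ccnb1, a mitotic cyclin, at 4.26 (SE 1.22, limma adjusted p = 0.418) (camera adjusted p = 4.94e-10, adjusted p = 0.752 with an estimated correlation). Neutrophil markers had a median of 2.62 with 3 passing adjusted over the list alone, and Ltf (3.76, limma adjusted p = 0.421) and Mmp8 (3.89, limma adjusted p = 0.421) led them (camera adjusted p = 8.96e-06, adjusted p = 0.752 with an estimated correlation). Ribosomal genes had a median of -0.95 (2.2e-10, adjusted p = 0.918 with an estimated correlation) and oxidative phosphorylation -0.83 (8.96e-06, adjusted p = 0.752 with an estimated correlation). Antigen presentation had -0.58 (0.00522, adjusted p = 0.918 with an estimated correlation) and immediate early genes 0.96 (0.0363, adjusted p = 0.918 with an estimated correlation). The macrophage gene Ms4a7 was at -3.81 (SE 0.78, limma adjusted p = 0.263) and Socs2, a STAT5 target, at -3.21 (SE 0.85, limma adjusted p = 0.382). The CSF genes were Csf1r at 0.45, Csf1 at 0.71, Csf3r at 0.90, Csf2ra at 0.01, Csf2rb at 0.05, Csf2rb2 at 0.05 and Il3ra at -1.50, none of which passed, and those of Csf2ra, Csf2rb and Csf2rb2 turned negative on median-centred values. The count was 0 without Csf1r_het replicate 1 or any Csf2_het replicate (1199 to 1375 at an unadjusted p under 0.05), 1 without Dhet replicate 1, a lower gene in place of Rps3a2, 6 without WT replicate 2 (3 higher, 3 lower) and 121 without Dhet replicate 2 (3 higher, 118 lower). The antigen presentation call was lost without Csf1r_het replicate 2 (0.137) or Dhet replicate 2 (0.114) and the immediate early call without WT replicate 2 (0.0516), Csf1r_het replicate 2 (0.173) or Dhet replicate 1 (0.83), where it turned direction. The antigen presentation median was -0.19 without Dhet replicate 2, the immediate early median -0.02 without Dhet replicate 1 and 1.77 without Dhet replicate 2, and the neutrophil median 1.71 without Csf1r_het replicate 2.

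Dhet against Csf2_het asks what loss of a Csf1r copy adds when a Csf2 copy is already lost. Of all genes tested 3 rose and 0 fell. Among the 3 were the glycogen phosphorylase Pygl (3.12, SE 0.38, limma adjusted p = 0.0114) and the transcription factor Nfe2 (2.43, SE 0.35, limma adjusted p = 0.0456). Pygl was 305 ± 132 in Csf2_het (n = 3) and 2511 ± 352 in Dhet (n = 2). EdgeR called 3 higher and 0 lower and DESeq2 129 and 50, and limma had 1083 genes at an unadjusted p under 0.05. Monocyte markers had 8 of 8 positive and a median of 2.37, with 6 passing adjusted over the list alone and Ly6c2 at 2.35 (SE 0.46, limma adjusted p = 0.129) (camera adjusted p = 4.78e-11, adjusted p = 0.173 with an estimated correlation). A second list of 18 monocyte genes, added after the data were seen, had a median of 0.86 with 0 that passed (unadjusted camera p = 0.000735, and 0.171 with an estimated correlation). Proliferation genes had 23 of 23 positive and a median of 2.23, with 9 passing adjusted over the list alone, and Mki67 at 2.81 (SE 0.62, limma adjusted p = 0.199) and Birc5 at 2.58 (SE 0.66, limma adjusted p = 0.288) (camera adjusted p = 1.8e-14, adjusted p = 0.343 with an estimated correlation). Neutrophil markers had a median of 2.64 with 3 passing adjusted over the list alone, Cxcr2 at 4.16 (limma adjusted p = 0.283) and Mmp8 at 4.64 (limma adjusted p = 0.339) (camera adjusted p = 1.35e-07, adjusted p = 0.583 with an estimated correlation). Oxidative phosphorylation had a median of -0.62 (5.58e-05, adjusted p = 0.583 with an estimated correlation) and ribosomal genes -0.43 (0.00225, adjusted p = 0.957 with an estimated correlation). Clec12a was at 1.99 (SE 0.36, limma adjusted p = 0.123) and Ms4a7 at -3.32 (SE 0.78, limma adjusted p = 0.233). None of the CSF genes passed, with Csf1r at -0.77, Csf1 at 0.49, Csf3r at 0.29, Csf2ra at 0.36, Csf2rb at 0.43, Csf2rb2 at 0.37 and Il3ra at 0.11, the last of which turned negative on median-centred values. The count was 0 without Csf2_het replicate 2 (942 unadjusted) or Csf2_het replicate 3 (748 unadjusted), 5 without WT replicate 2 (4 higher, 1 lower) and 85 without Dhet replicate 2 (3 higher, 82 lower). Without Dhet replicate 1 it was 2 (1 higher, 1 lower). The ribosomal call was lost without Csf2_het replicate 3 (0.119) or Dhet replicate 2 (0.587). The ribosomal median ran from -0.65 without Csf2_het replicate 2 to -0.23 without Csf2_het replicate 3, and the oxidative phosphorylation median was -0.38 without Dhet replicate 1.

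The interaction asks whether the effect of a lost Csf1r copy differs between the Csf2 genotypes. It was positive where the Dhet level lay above the sum of the changes of the single heterozygotes. C3 (3.57, SE 0.65, limma adjusted p = 0.0193), Itgb2 (2.50, SE 0.46) and Cfp (4.55, SE 0.91) of the complement list, Cybb (2.76, SE 0.41, limma adjusted p = 0.00874), Rac2 (2.27) of the oxidase genes, Plin2 (2.54), Tgfbi (3.54), Slfn2 (2.81) and Slc16a3 (3.46) had a positive interaction. Trem2 (-2.11, SE 0.48, limma adjusted p = 0.0427), the tetraspanin Cd63 (-2.16), the peroxidase Gpx4 (-2.22) and Socs2 (-5.19) had a negative one. Of 8 monocyte markers all were positive and 5 passed over all genes, among them F13a1 (4.93, SE 0.87), with 7 adjusted over the list alone and a median of 3.83 (camera adjusted p = 1.53e-07, adjusted p = 0.404 with an estimated correlation). The largest other positive values were those of Pxylp1 (7.89), Tarm1 (7.39), Slco3a1 (6.88), the inhibitory receptor relative Pira2 (5.73), Glipr2 (5.49), Slc22a15 (5.29), the sphingosine phosphate receptor S1pr4 (5.15) and Pygl (5.05). The largest other negative values were those of Spink8 (-11.64), Hmgcll1 (-9.70), the matrix proteoglycan Bgn (-7.74), Tmem14a (-4.51), the growth factor Mdk (-4.09), Frmpd1os (-4.04) and Gsta4 (-3.99). Csf2rb was at 1.92 (SE 0.48, limma adjusted p = 0.0627), Csf2ra at 1.64, Csf2rb2 at 0.77, Csf1r at 0.53, Csf1 at 0.25, Csf3r at 1.03 and Il3ra at 0.64, none of which passed.

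In all, 159 genes had a positive and 85 a negative interaction, and on median-centred values 119 and 122. Without Dhet replicate 2 the split turned to 77 positive and 170 negative, and 126 of the 244 calls remained. For 244 of the 244 both single-heterozygote changes pointed opposite to the interaction, which partly follows from the WT libraries entering all 3 contrasts, and 185 of them were also called in Csf2_het, 122 in Csf1r_het and 16 in Dhet. Among the lists, proliferation had a median of 2.94 (camera adjusted p = 6.18e-05, adjusted p = 0.792 with an estimated correlation). Immediate early genes had 1.80 with 3 of 17 called, among them Klf2 (2.97) and Ier2 (2.56) (6.18e-05, adjusted p = 0.792 with an estimated correlation). Neutrophil markers had 3.12 (0.000355, adjusted p = 0.792 with an estimated correlation) and oxidative phosphorylation -1.21 (2.07e-05, adjusted p = 0.792 with an estimated correlation). Homeostatic genes had -0.81 with 0 of 19 called (0.00211, adjusted p = 0.792 with an estimated correlation) and disease-associated genes -0.55 with 2 of 23 called (0.018, adjusted p = 0.792 with an estimated correlation). Clec12a was also positive (2.70, SE 0.49, limma adjusted p = 0.0191). The count of 244 was 61 without WT replicate 1, 911 without WT replicate 2, 106 and 78 without Csf1r_het replicates 1 and 3, 70, 95 and 86 without Csf2_het replicates 1, 2 and 3 and 47 without Dhet replicate 1. Of 32 named interaction calls, 4 held in every such fit, namely Pira2, Pygl, Mdk and Plin2. The homeostatic call was lost without WT replicate 2 (0.094) or Dhet replicate 2 (0.176) and the disease-associated call without Dhet replicate 2 (0.343). Without that library their medians were -0.43 and -0.33. The immediate early median was 1.19 without Dhet replicate 1 and the neutrophil median 1.98 without Csf1r_het replicate 2.

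The 174 genes called in Csf1r_het were then followed into Dhet, to ask whether Dhet lay nearer WT. Their median change in the Csf1r_het direction was 1.88 in Csf1r_het, 1.13 in Dhet and 1.88 in Csf2_het, and 147 of 174 (84.5%) had a smaller absolute change in Dhet. Of the 174, 170 kept their sign in Dhet, 29 were called in Dhet against WT and 0 in the direct limma comparison of Dhet with Csf1r_het (1390 genes of all had an unadjusted p under 0.05 there). Genes picked for a large change in 1 group tend to show a smaller one in another. In 100 simulations with equal true effects, made from whole-library residuals of which none was used more than once per simulation, the share ranged from 21.3% to 94.8% with a mean of 64.2%, and 17 reached the observed share. With no effect in Dhet it was 100% in every simulation. The residuals of the 2 Dhet libraries are exact mirror images, so drawing both could place the same deviations in 2 groups. The range for equal effects may be too wide for that reason. An earlier reference that drew genes independently gave 60.9% to 76.4%, and was replaced, after its result was seen, because genes move together within libraries. A further one that drew libraries with replacement, and so could place 1 library in 2 groups, gave 17.8% to 92.5% with 14 reaching the observed share. The share was 73.1% without the 24-month libraries.

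The comparisons against WT share the WT libraries. The log2 fold changes of Csf1r_het and Csf2_het correlated across 13223 genes with Pearson's r = 0.678 (Spearman 0.696) and a covariance of 0.962, those of Csf1r_het and Dhet with r = 0.423 and 0.600, and those of Csf2_het and Dhet with r = 0.508 and 0.767. Genes are not independent replicates. In 100 simulations of unchanged groups against shared controls, r averaged 0.475 (-0.163 to 0.962) and the covariance 0.421 (-0.121 to 1.30), and 7, 26 and 11 simulations reached the covariances above. Both called higher in Csf1r_het and Csf2_het were 44 genes, against 0.461 for independent lists, and both called lower 104, against 3.32. For Csf1r_het and Dhet these were 0 (0.0172) and 29 (0.584), and for Csf2_het and Dhet 4 (0.0324) and 55 (1.87). The 3 WT libraries cannot be split into parts of at least 2, so part of each excess may come from the shared controls. Contrasts without a shared library gave r = -0.257 for Csf1r_het minus WT against Dhet minus Csf2_het and r = -0.124 for Csf2_het minus WT against Dhet minus Csf1r_het, within the range of -0.749 to 0.987 simulated without effects. Both sets of simulations drew on residuals in which the 2 Dhet libraries mirror each other. The latter set always drew both, so its range may be too wide to judge these values.

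The remaining fixed lists passed in none of the 6 contrasts. Against WT, their medians in Csf1r_het, Csf2_het and Dhet were -0.20, 0.16 and 0.46 for CSF-2 and STAT5 response genes, 0.37, 0.15 and 0.29 for inflammatory cytokines. They were -0.30, 0.06 and 0.10 for complement, whose sign in Csf2_het and Dhet turned with edgeR and DESeq2 scaling, -0.16, 0.15 and 0.14 for lysosome genes, -0.56, -0.18 and -0.39 for TGF-beta signalling and 0.42, 0.62 and 0.45 for neurotrophic genes. They were 1.69, 1.34 and 1.91 for the 1 tested marker of oligodendrocyte precursors, -0.04, -0.27 and -0.38 for endothelial markers, whose sign in Csf1r_het turned with scaling. They were 1.12, -0.09 and 0.23 for mural and fibroblast markers, -0.23, -0.90 and -1.08 for T and NK cell markers, 0.86, 0.60 and -0.27 for border macrophage markers, 0.82, 0.39 and -0.18 for erythroid markers and 0.78, 0.64 and 3.16 for sex-linked genes. None of these 39 medians was stable with each library left out in turn: 24 turned sign in at least 1 fit and the other 15 moved by over 1.5 times. For example, the mural and fibroblast median in Csf1r_het was 0.021 without Csf1r_het replicate 2, the T and NK cell median in Csf2_het -0.24 without WT replicate 2 and the CSF-2 and STAT5 median in Dhet -0.27 without WT replicate 2. The sex-linked value in Dhet rested on Dhet replicate 2, since it was 0.72 without Dhet replicate 2 and 5.63 without Dhet replicate 1.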

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

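The tests of blood carried into the sort, of immature neutrophil-lineage cells, of Dhet replicate 2 alone and of the Rps3a reads were chosen only after the results were seen, and the tests of other splits of the libraries before. The second monocyte list was added after the data were seen, and its test was set before its values were.

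The change in libraries lacking a Csf1r copy differed between the Csf2 genotypes, by the limma interaction test, for 244 genes. Among named genes the interaction was positive, on the log2 scale, for Nfil3 (3.51), Slc16a3 (3.46), Pirb (4.20), Rasgrp4 (3.27), Itgb2 (2.50), C3 (3.57), Cybb (2.76), Plin2 (2.54), Tgfbi (3.54), Klf2 (2.97), Dusp1 (3.53), Slco3a1 (6.88), Tarm1 (7.39), Slfn2 (2.81), Cfp (4.55), Rac2 (2.27), Ccr2 (3.23), Clec12a (2.70), Pygl (5.05), Nfe2 (4.08), Ly6c2 (2.88), Pxylp1 (7.89), Pira2 (5.73), Glipr2 (5.49), Slc22a15 (5.29), S1pr4 (5.15), Ier2 (2.56) and F13a1 (4.93). It was negative for Pifo (-3.52), Fam92a (-3.20), Gsta4 (-3.99), Cystm1 (-3.09), Trem2 (-2.11), Spink8 (-11.64), Hmgcll1 (-9.70), Socs2 (-5.19), Bgn (-7.74), Tmem14a (-4.51), Mdk (-4.09), Frmpd1os (-4.04), Cd63 (-2.16) and Gpx4 (-2.22). Lists of other cells shifted too, with an interaction median of 3.83 for monocyte markers and -2.51 for choroid plexus genes. The choroid plexus list was added after the data were seen. Whether the called genes share a source with these lists was not tested. The WT libraries enter the interaction and both single comparisons, and without WT replicate 2 the count was 911, without Dhet replicate 1 it was 47, and the values without the other libraries stand with the comparison.

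The 8 tested monocyte markers fell in Csf2_het, with a list median of -3.21 (camera adjusted p = 4.49e-12, adjusted p = 0.128 with an estimated correlation). A second list of 18 monocyte genes, which held none of the first, had a median of -2.42 with 10 that fell (unadjusted camera p = 0.00543 with an estimated correlation). It had -1.34 with 0 in Csf1r_het (0.0324) and -1.81 with 2 in Dhet (0.014), so it was below 0 in all 3 heterozygous groups. Fewer monocyte-lineage cells in the Csf2_het sort are a candidate explanation. The Tmem119 gate is meant to exclude such cells, yet the mean log2 level of monocyte markers in WT was 12.6, with 13.4 for homeostatic genes. These levels show that monocyte transcripts were present and do not give cell shares. The erythroid marker mean changed by 0.318 (SE 0.698), whose spread leaves open whether less blood was carried into the Csf2_het sort. Marker means of other blood cells were lower in Csf2_het than in WT. They changed by -1.41 (SE 0.624) for T and NK cells, -1.92 (SE 1.09) for B cells and -1.04 (SE 1.23) for neutrophils. Lower expression of the monocyte genes in the sorted cells, by Csf2 genotype, was not tested and stays open.

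The proliferation list had a median of 2.0 in Dhet against WT, with 0 of 23 genes that passed over all genes (camera adjusted p = 4.87e-11, adjusted p = 0.372 with an estimated correlation). The median was 1.56 without Dhet replicate 2, which argues against that library alone as the source. Its sex is not given in the labels used here, but its high Ddx3y (717) and low Xist (4.02) are the pattern of a male. All other libraries showed the opposite pattern. The Dhet comparisons and the interaction therefore mix sex with genotype, which 2 Dhet libraries cannot separate. Across the 11 libraries the deviations of the proliferation and neutrophil means from their group means correlated with Pearson's r = 0.862 (exact permutation p = 0.0231 over 432 permutations within groups) and Spearman's rho = 0.864 (p = 0.0185), with r = 0.784 without WT replicate 3 and Csf1r_het replicate 2, in the 1 relation computed. Dividing neutrophil-lineage cells in the libraries may thus account for part of this shift. The Tmem119 gate is meant to exclude them, yet the neutrophil mean in Dhet was 14.8, with 14.2 for homeostatic genes. Levels of different lists do not give cell shares, so these values show only that such transcripts were present. WT replicate 3 had a higher neutrophil mean (15.09) than either Dhet library (14.79 each) but a lower proliferation mean, 8.29 against 9.03 and 9.77. The neutrophil means of the 2 Dhet libraries were nearly equal, so Dhet adds almost nothing to the correlation. Dividing microglia in Dhet were not tested and stay open.

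Rps3a2 and Rps3a3 were high in each of the 5 Csf2+/- libraries, at 1094 normalized counts of Rps3a2 or more against at most 9.47 in the 6 others. The share of pseudogenes that separated the Csf2 genotypes completely was 1.77%, against 1.29% of other genes (Fisher's exact p = 0.458, taken over genes and not mice) and 0.433% by chance, which argues against a shift of all pseudogenes. The log2 change of the summed Rps3a1, Rps3a2 and Rps3a3 was -0.98 (SE 0.363), which minus the ribosomal list median gave -0.15, and Rps3a1 lost 8351 normalized counts while its copies gained 1917. A candidate explanation is that reads moved between Rps3a1 and its copies. The gain of the copies lay below the Rps3a1 count of every library (at least 3144). With its SE, the sum therefore cannot tell moved reads from expression of the copies themselves. A sequence variant linked to the Csf2 allele was not tested, since it needs reads.

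For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 174 genes in Csf1r_het, against at most 1 in the other splits, and 482 in Csf2_het, against at most 0. In each case 1 split, the real one, gave as many.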

How the results depend on the processing

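The edgeR test, the monocyte covariate and leaving out Csf1r_het replicate 2 and WT replicate 2 together were chosen after seeing the data, and the other alternatives before. Of 186 results for named genes, 156 kept their direction in every alternative run, and counts of calls moved more than directions. The causes were not tested, except that fewer libraries leave fewer degrees of freedom. The monocyte mean largely follows the groups, so its slope was fitted from differences within groups and carried over the gap between them. Such a fit can push a change past 0, as for the homeostatic median in Csf2_het (1.09 to -0.53). It cannot tell group from monocyte content. Counts below are limma calls unless another tool is named. Depth limits the low genes, where 1 read is worth 0.479 to 1.48 normalized counts. Of the libraries at 24 months, Csf1r_het replicate 2 had the highest share of haemoglobin counts (58.8%). The other, Dhet replicate 2, stood apart in sex-linked genes. Fits with age as a covariate or without these libraries cannot tell age from those traits.

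In the order Csf1r_het, Csf2_het, Dhet, Dhet against Csf1r_het, Dhet against Csf2_het and interaction, the main counts were 174, 482, 70, 1, 3 and 244. DESeq2 called 828, 1238, 361, 118, 179 and 995. EdgeR called 100 in Csf1r_het, 26 in Dhet and 2 for Dhet against Csf1r_het. At an adjusted p of 0.01 the counts were 6, 150, 6, 0, 0 and 35, and at 0.1 they were 406 in Csf1r_het, 859 in Csf2_het, 3 for Dhet against Csf1r_het and 581 for the interaction. With only the 2 groups compared in the fit they were 0 in Csf1r_het (1717 at an unadjusted p under 0.05), 259 in Csf2_het, 0 in Dhet (966 unadjusted), 0 for Dhet against Csf1r_het (1609 unadjusted) and 0 for Dhet against Csf2_het (1511 unadjusted). With age as a covariate they were 70 in Csf1r_het and 0 for Dhet against Csf2_het (1446 unadjusted). Without the 24-month libraries they were 26 in Csf1r_het, 310 in Dhet, 200 for Dhet against Csf1r_het, 221 for Dhet against Csf2_het and 392 for the interaction. With the monocyte marker mean as a covariate they were 0 in Csf1r_het (837 unadjusted), 0 in Csf2_het (432 unadjusted), 1 in Dhet, 0 for Dhet against Csf2_het (968 unadjusted) and 0 for the interaction (898 unadjusted). Without both libraries farthest from the others they were 583 in Csf1r_het, 953 in Csf2_het, 8 for Dhet against Csf1r_het, 71 for Dhet against Csf2_het and 1340 for the interaction. A pseudocount of 0.1 gave 0 for Dhet against Csf1r_het (1329 unadjusted), and a pseudocount of 10 gave 3 there and 6 for Dhet against Csf2_het.

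Lists called by camera numbered 10, 13, 16, 6, 5 and 7 in the same order. At an adjusted p of 0.01 there were 6 in Csf1r_het, 7 in Csf2_het and 8 in Dhet, and at 0.1 there were 9 for Dhet against Csf2_het and 11 for the interaction. With an estimated correlation there were 0 in each, and fry called 1, 4, 1, 0, 1 and 2. Without the 24-month libraries there were 11 for Dhet against Csf1r_het. Medians of called lists that turned with the monocyte covariate, other than those of the monocyte markers, were homeostatic (-0.051) and astrocyte (-0.82) in Csf1r_het, homeostatic (-0.53), disease-associated (-0.23), interferon (0.17), ribosomal (1.75), astrocyte (-2.70) and B cell (3.02) in Csf2_het, astrocyte (-0.34) in Dhet and homeostatic (0.58) for the interaction. The share of Csf1r_het genes with a smaller change in Dhet was 73.1% without the 24-month libraries.

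The replicate numbers did not pair the libraries. Of 15 pairs with the same number, 0 had deviations that correlated above 0.1 (-0.214 to 0.0616), and 0 of 11 libraries correlated best with their own number. With the replicate block the counts were 28 in Csf1r_het, 256 in Csf2_het, 0 for Dhet against Csf1r_het (1266 unadjusted), 0 for Dhet against Csf2_het (863 unadjusted) and 14 for the interaction, and the share was 60.7%. The block also turned Csf2ra (-0.075), Csf2rb (-0.028) and Csf2rb2 (-0.040) for Dhet against Csf1r_het and Il3ra (-0.17) for Dhet against Csf2_het. With it the glycolysis and astrocyte calls in Csf1r_het were lost (camera adjusted p = 0.0509 each). So were the oxidative stress call in Dhet (0.0729) and the immediate early call for Dhet against Csf1r_het (0.0536).

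Leaving out each library in turn gave 0 to 442 calls in Csf1r_het, 172 to 675 in Csf2_het, 2 to 174 in Dhet, 0 to 121 for Dhet against Csf1r_het, 0 to 85 for Dhet against Csf2_het and 47 to 911 for the interaction. The lists called ranged over 7 to 13, 11 to 14, 9 to 17, 5 to 9, 5 to 8 and 7 to 12, and the share over 73.6% to 91.9%. A Dhet group left with 1 library was assumed to vary like the others. Log2 changes that turned ranged over -0.19 to 0.54 for Csf1 in Csf1r_het, -0.37 to 0.21 for Csf1r and -0.54 to 0.088 for Csf3r in Csf2_het, and -1.53 to 0.83 for Csf2rb2 and -0.26 to 0.38 for Csf3r in Dhet. For Dhet against Csf1r_het they were -0.28 to 0.31 for Csf2ra, -0.23 to 0.32 for Csf2rb and -1.13 to 1.23 for Csf2rb2. For Dhet against Csf2_het they were -0.19 to 1.18 for Csf1, -0.81 to 1.55 for Csf2rb2 and -0.36 to 0.58 for Il3ra, and for the interaction -0.44 to 0.93 for Csf1 and -0.41 to 1.95 for Csf2rb2.

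Other log2 changes that turned were mostly small or came with the monocyte covariate. In Csf1r_het, Csf1 was -0.068 without the 24-month libraries, -0.78 with the monocyte covariate and -0.51 without both libraries farthest from the others, and Il3ra was 0.18 with the monocyte covariate. In Csf2_het, Csf1r was 0.0055 on median-centred values, and with the monocyte covariate Csf1 was -2.25, Spink8 -0.11, Sbspon -0.80, Ttll4 -0.22, Tlr8 1.31, Siglech -0.068, Sall1 -0.53, Spp1 -0.41, Slfn2 0.27, Zbp1 0.31, H2-Ab1 0.33, H2-Aa 1.12 and Ccr2 0.16. In Dhet, Csf1 was -0.063 with the monocyte covariate, Csf2rb2 was 0.098 with DESeq2, 0.073 with edgeR and 0.83 without the 24-month libraries, and Csf3r was -0.051 without the 24-month libraries, -0.20 with the monocyte covariate and -0.26 without both libraries farthest from the others. For Dhet against Csf1r_het, Csf2ra was -0.033 with DESeq2, -0.028 with edgeR, -0.15 on median-centred values, -0.022 with age, -0.33 without the 24-month libraries and -0.033 without both libraries farthest from the others. Csf2rb was -0.073 with DESeq2, -0.063 with edgeR, -0.11 on median-centred values and -0.074 with age, and Csf2rb2 was -0.11 on median-centred values. For Dhet against Csf2_het, Csf2ra was -0.60 with the monocyte covariate, and Il3ra was -0.0024 on median-centred values, -0.58 with age, -0.36 without the 24-month libraries and -1.08 with the monocyte covariate. Il3ra was -1.26 for the interaction with the monocyte covariate.

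Centring each library moved the median of all genes from -0.12 to 0.0056 in Csf1r_het, from 0.10 to -0.059 for Dhet against Csf1r_het, from 0.029 to -0.081 for Dhet against Csf2_het and from 0.15 to -0.092 for the interaction. Not run were a recomputed adjustment and a shrunken fold change, which apply to a table of comparisons, a second scaling factor in edgeR as an alternative of its own, an estimated correlation or fry for the share of smaller changes, which is no list test, and a fit of only 2 groups for the interaction, which needs 4. The share had no value without WT replicate 1 or Csf1r_het replicate 3, where no Csf1r_het call remained.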

Other observations

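The choroid plexus and immature granulocyte lists were added, and their tests chosen, only after the data were seen, so they describe these libraries and are no independent evidence.

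Few genes of the choroid plexus, the epithelium that makes cerebrospinal fluid, passed in the single heterozygotes. The 10 tested genes had a median log2 fold change of 1.61 in Csf1r_het with 2 that rose (unadjusted camera p = 4.16e-07, and 0.042 with an estimated correlation), 1.26 in Csf2_het with 1 that rose (2.93e-05, and 0.0796 with an estimated correlation) and 0.15 in Dhet with 0 (0.205, and 0.554 with an estimated correlation). For the interaction the median was -2.51 with 2 called negative (2.83e-07, and 0.0399 with an estimated correlation). The thyroxine carrier Ttr had 266800, 627600 and 337400 normalized counts in WT, 1120000, 782000 and 1409000 in Csf1r_het, 900700, 730100 and 1104000 in Csf2_het and 226100 and 438300 in Dhet. The folate receptor Folr1 had 4272, 1567 and 3610 in WT, 12610, 7222 and 12370 in Csf1r_het, 7305, 8750 and 5635 in Csf2_het and 2386 and 4339 in Dhet.

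Genes of immature granulocytes, which are made in the bone marrow, varied widely between libraries of a group. The mean log2 level of their 8 tested genes was 10.85 and 12.09 in Dhet, 8.51, 6.57 and 10.50 in WT, 5.44, 6.29 and 10.80 in Csf1r_het and 6.94, 8.71 and 5.48 in Csf2_het. The myeloperoxidase gene Mpo had 3630 and 14120 normalized counts in Dhet, 1831, 6.79 and 2219 in WT, 14.5, 416 and 3543 in Csf1r_het and 74.1, 1028 and 2.73 in Csf2_het. Unlike Mpo, Elane, Prtn3 and Ctsg were higher in Csf1r_het replicate 3 (6781, 2718 and 2351) than in Dhet replicate 1 (4869, 1299 and 807). The list median in Dhet against WT was 3.25 with 0 genes that passed in limma (unadjusted camera p = 0.000586, and 0.17 with an estimated correlation).

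The predicted gene Gm28438 also separated the Csf2 genotypes, with 62330, 14510 and 1608 normalized counts in Csf2_het and 23300 and 3964 in Dhet, against at most 131 in the 6 other libraries. Its level varied widely among the Csf2+/- libraries, unlike those of Rps3a2.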
